A study of Mus musculus with 8 samples.

How the data were processed

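Germline stem cells were derived from testes of Green mice, a line that carries an enhanced green fluorescent protein transgene, on a DBA/2 background. They were grown for about 5 or 60 months in medium with FGF2, GDNF and fetal bovine serum, per the labels' protocols. Chromatin was cross-linked with formaldehyde and fragmented by sonication, with or without micrococcal nuclease, and the labels do not say which libraries received the nuclease. It was precipitated with antibodies against H3K4me3 or H3K27me3, and the libraries were sequenced on an Illumina HiSeq instrument. Per the labels, each mark and age has 2 libraries. They do not say whether the libraries came from separate cultures, so the spread between them may be technical.

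Per the submitters' processing notes, CASAVA 1.8.4 and Bowtie 1.1.2 were used and the genome build was mm10. The peak caller is not given in the sources used here. The authors deposited one peak list per library, called per library and not on pooled libraries. Each list gives borders in bins of 1000 bp and, per the file headers, a maximum immunoprecipitation signal, used here as the strength of a peak. The deposited lists also give 2 columns of −log10 p-values, for the immunoprecipitate alone and against the control, and a q-value, per the file headers. The −log10 p against the control ran from 3.01 to a ceiling of 15.95, which 69.9 ± 0.385% of the H3K4me3 peaks at 5M and 77.0 ± 2.07% at 60M reached (SD, n = 2), so strength was ranked by signal. The highest q-value was 0.00097. How the authors scaled the signal is not given in the sources used here. It was therefore turned into a percentile within each list and not compared across libraries in the main results. Read totals are not given in the lists, so depth is unknown. A peak missing from a list was not called there, which does not show that the mark is absent.

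The positions run past the build that the notes name. On 9 of 20 chromosomes peaks end beyond the mm10 chromosome (1331 peaks over the 8 lists). They fit the mm9 lengths on all chromosomes except 13, where the last bin overhangs by 688 bp. Chromosome lengths came from GenomeInfoDb 1.38.1. The gene table at hand is for another assembly (GRCm38.p6), and positions were not converted. Gene names, promoter counts, gene lists and cell type markers, which had been planned, were therefore not analysed here, and results stay at the level of regions and chromosomes.

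Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures matplotlib 3.10.9. Peaks of the 4 libraries of a mark were merged where they shared at least 1 bp. A region was called 60M-only when both 60M libraries and neither 5M library had a peak in it, and 5M-only for the reverse. As the replicate error of these counts, the same count was made for the 2 other ways of splitting 4 libraries into pairs. A permutation test of 2 libraries against 2 has 6 arrangements and a smallest two-sided p of 0.333, so it was not used to make calls. Shared regions counted as wider when both libraries of one age covered more bases than both of the other. Broad peaks were those of at least 5 kb for H3K4me3 and 10 kb for H3K27me3. Overlap between libraries was the Jaccard index of covered bases.

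The rule for named items, fixed before the data were examined, took the 12 per mark and direction with the highest mean strength percentile. It was written for promoters and applied to regions. The examples of broad peaks, of regions with both marks and of the chromosome 18 window were chosen after their values were seen. For both marks together, the planned unit was the promoter. Here the unit was an H3K4me3 region, and a mark counted as present at an age when both libraries had a peak that overlapped it. Fisher's exact tests and their odds ratios take regions as units, and shares have exact binomial (Clopper-Pearson) 95% intervals. The test of H3K27me3 regions on and off H3K4me3 peaks, the width and broad peak counts and the window test were added after the data were examined. Windows of 1 Mb were tested for an excess of regions of one age with a one-sided Fisher's exact test (the hypergeometric tail), adjusted over the 9996 tests of both marks and directions within a split. A further version matched regions on strength, in classes of 5 percentiles of the highest percentile in any library, and used an exact Poisson-binomial test. Tests of 3 explanations for the regions that lost both marks were run and are left out here, a choice made after their values were seen.

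The code of the region calls was run on simulated lists with 200 regions planted per mark and direction. With 5% of all H3K4me3 peaks missed at random, 183 of the 200 60M-only and 182 of the 200 5M-only regions were recovered, where the misses alone leave 180.5. With 30% of H3K27me3 peaks missed, 101 and 88 were recovered, where the misses leave 98. These rates follow from the misses put in and do not measure the sensitivity of the real lists. Regions without a planted change were also called 60M-only and 5M-only, 78 and 71 of 31475 simulated H3K4me3 regions and 150 and 162 of 3966 H3K27me3 regions. The alternatives were lists shortened to the same length (41637 and 12002 peaks), the peaks above the median strength of each list or of the pooled list, merging within 1 kb, cover of at least 50% of a region, autosomes only, minimum strengths and leaving out each library in turn.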

Results

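The data were chromatin immunoprecipitation sequencing profiles of 2 histone marks in mouse germline stem cells, the cultured form of spermatogonial stem cells. H3K4me3 is found mainly at active or poised promoters. H3K27me3 is deposited by Polycomb repressive complex 2 and is found at silenced genes. Cells grown for about 5 months (5M) were compared with cells grown for about 60 months (60M), with 2 libraries for each mark and age and 8 libraries in all. The series title names aging of spermatogonial stem cells through Wnt7b and Jnk, and the comparison asks how the distribution of both marks differs after long culture. One list of peaks was used per library. The lists held 41637 to 47415 peaks for H3K4me3 and 12002 to 14940 for H3K27me3, on 19 autosomes and the X chromosome. They give no read totals, so the sequencing depth of each library is unknown. Positions are given as listed, with borders at steps of 1000 bp, and follow the chromosome lengths of mm9. No annotation of that build was used, so regions are named by position alone and no gene, exon or intron is assigned to them.

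In the lists as given, H3K4me3 peaks were fewer and wider in 60M cells, and H3K27me3 peaks were narrower. For H3K4me3, 5M cells had 46674 ± 1048 peaks (SD, n = 2) and 60M cells had 42668 ± 1458. The mean H3K4me3 peak width was 2.12 ± 0.0216 kb at 5M and 2.27 ± 0.0312 kb at 60M, and peaks of a single 1 kb bin made up 31.1 ± 0.279% and 24.6 ± 1.77% of the lists. Because fewer peaks were wider, the covered length differed by less than the spread between replicates, at 98.9 ± 3.23 Mb and 96.9 ± 1.98 Mb. For H3K27me3, the peak number overlapped between ages, at 13317 ± 1860 and 13989 ± 1346, and so did the covered length, at 30.3 ± 6.37 Mb and 27.5 ± 2.87 Mb. The mean H3K27me3 width was 2.27 ± 0.162 kb at 5M and 1.96 ± 0.0161 kb at 60M, and both 5M libraries lay above both 60M libraries. At equal list lengths the H3K4me3 width difference of 0.154 kb fell to 0.0628 kb. For each of these measures in which the ages did not overlap, an exact two-sided permutation test gave p = 0.333, the smallest that 2 libraries against 2 allow.

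**Figure D1:**
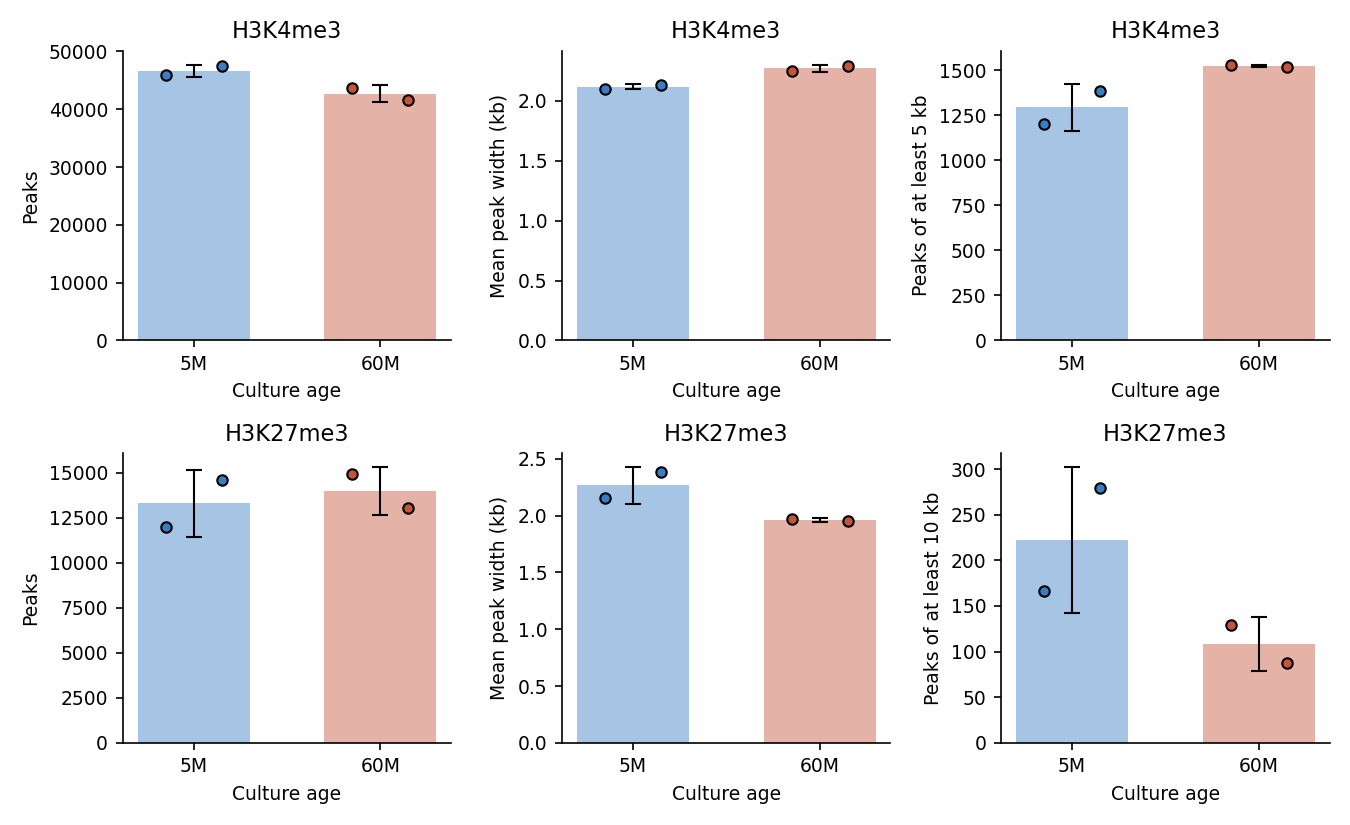
Number of peaks, mean peak width in kb and number of broad peaks (at least 5 kb for H3K4me3, at least 10 kb for H3K27me3) in 5M and 60M cells; bars are means of 2 libraries, error bars SD and points single libraries. H3K4me3 width rose from 2.12 to 2.27 kb and H3K27me3 width fell from 2.27 to 1.96 kb, with no overlap between the ages.

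Libraries of one age resembled each other more than libraries of the other age. The Jaccard index of the covered bases was 0.888 between the H3K4me3 libraries at 5M and 0.837 between those at 60M, against 0.735 to 0.760 for the 4 pairs across ages. For H3K27me3 the indices were lower throughout, with 0.519 at 5M, 0.437 at 60M and 0.370 to 0.401 across ages.

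H3K4me3 regions listed at one age only were found in both directions, with more at 5M in the lists as given. Merging the peaks of the 4 libraries gave 54585 H3K4me3 regions, of which 35229 (64.5%) were listed in all 4. A set of 5509 regions (10.1%) was listed in both 5M libraries and neither 60M library, and 2437 regions (4.46%) in both 60M libraries and neither 5M library. Pairs of libraries that mixed the ages shared far fewer, with 223 against 141 in one split and 85 against 160 in the other. The age split gave 7946 regions in total, 21.8 times the highest other total of 364. Most of these regions were weak, with a median strength percentile within their own lists of 21.7 for the 5M-only and 13.5 for the 60M-only regions. Above the 50th percentile the imbalance was steeper, with 514 regions at 5M only, 24 at 60M only and 0 in the splits that mixed the ages. This cut within lists keeps more peaks of the longer 5M lists. The ratio of 5M-only to 60M-only regions was 2.26. It fell to 1.12, with 3952 and 3519 regions, when every list was shortened to its 41637 strongest peaks, and ran from 0.932 to 1.17 at that length with 1 library left out. Cutting the longer 5M lists lowers this ratio by construction, so its fall does not show the cause. At full length it was 1.42 without 60M library 2, when 4800 regions were 60M-only. Leaving out a library lets the other library of its age decide alone, so both counts rise by construction.

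**Figure D2:**
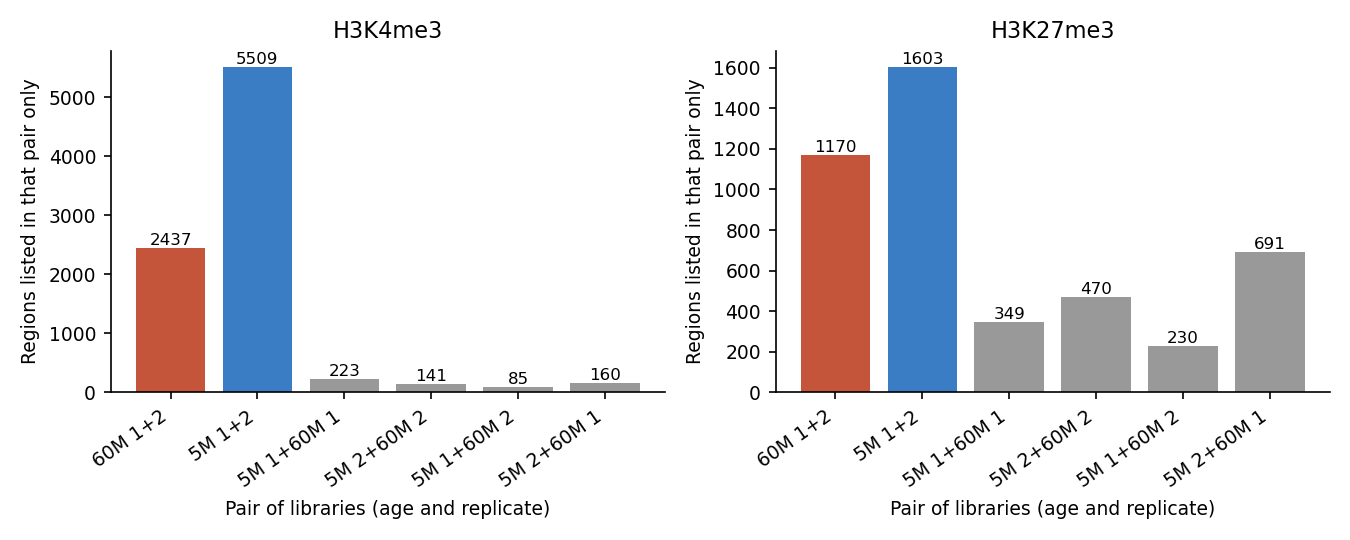
Number of merged regions listed in both libraries of the named pair and in neither of the other pair, for H3K4me3 and H3K27me3; coloured bars pair libraries of one age and grey bars mix the ages. For H3K4me3 the age pairs gave 2437 and 5509 regions against at most 223 for mixed pairs, and for H3K27me3 1170 and 1603 against at most 691.

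The 12 strongest H3K4me3 regions of each direction lay in the middle to upper part of their lists and had no H3K27me3 peak in any library. The same held for 4889 of all 5509 5M-only and 2299 of all 2437 60M-only regions. Among the 5M-only regions, a 3 kb region on chromosome 4 (139170000 to 139172999) reached signal maxima of 463.8 and 473.1 in the 5M libraries, and one on chromosome 16 (90010000 to 90012999) reached 440.4 and 482.9. The next regions lay on chromosome 10 (115550000 to 115551999), chromosome 15 (89165000 to 89167999), chromosome 4 (148938000 to 148939999), chromosome 19 (40399000 to 40401999) and chromosome 7 (6663000 to 6664999). A second region on chromosome 15 (89377000 to 89379999) was listed in the 5M libraries with maxima of 327.1 and 426.7. The remaining 4 of the 12 were on chromosomes 3, 4, 13 and 14, and the mean percentiles of the 12 ran from 73.1 to 80.5. Among the 60M-only regions, chromosome 2 (166350000 to 166352999) led with maxima of 435.7 and 446.1 in the 60M libraries. It was followed by a 1 kb region on chromosome 11 (96173000 to 96173999, 323.4 and 381.6), and by regions on chromosome 5 (123946000 to 123948999), chromosome 10 (44166000 to 44168999) and chromosome 4 (128664000 to 128667999). The other 7 were on chromosomes 4, 9, 13, 14, 15 and 17, and the percentiles of the 12 ran from 55.3 to 76.6. These maxima are the authors' values per peak and rank peaks within a list only.

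Regions with H3K4me3 in all 4 libraries were more often broader than narrower at 60M. In 2619 of the 35229 shared regions (7.43%) both 60M libraries covered more bases than both 5M libraries, and in 878 (2.49%) both covered fewer. Mixed splits held fewer regions, with 444 wider against 180 narrower and 430 against 167 for the pairs with 5M library 2, ratios (2.47 and 2.57) close to the 2.98 of the age split. Single 60M libraries against single 5M libraries gave ratios of wider to narrower regions of 1.67 to 2.89, and 5M library 2 against 5M library 1 gave 2.25. The mean covered length per shared region was 2.38 ± 0.0396 kb at 5M and 2.47 ± 0.00556 kb at 60M (SD, n = 2). Broad H3K4me3 peaks of at least 5 kb followed the same direction: 190 regions had one in both 60M libraries and neither 5M library, 71 the reverse, and mixed splits gave 13 against 21 and 4 against 22. On chromosome 17 (86012000 to 86023999) the widest peak measured 3 kb in both 5M libraries and 7 and 12 kb in the 60M libraries. On chromosome 15 (83898000 to 83906999) it measured 3 and 4 kb at 5M against 9 and 8 kb at 60M, and on chromosome 5 (117564000 to 117571999) 3 kb in both against 8 kb in both. In the other direction, regions on chromosome 10 (61290000 to 61297999) and chromosome 3 (96205000 to 96209999) held broad peaks at 5M and no peak at 60M.

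H3K27me3 regions also changed in both directions, with a larger share of disagreement between replicates. Of 26634 merged regions, 4962 (18.6%) were listed in all 4 libraries and 14599 (54.8%) in a single library. The number listed at 5M only was 1603, and 1170 were listed at 60M only. Mixed pairs gave 349 against 470 and 230 against 691, the larger numbers for the pairs with 5M library 2, so that the age total of 2773 was 3.01 times the highest other total of 921. Above the 50th percentile of strength, 665 regions were 5M-only and 397 were 60M-only, against at most 167 for a mixed pair. With 1 library left out, the ratio of 1.37 became 3.94 without 5M library 1 (5871 against 1489) and 1.88 without 5M library 2 (3618 against 1923). It was 0.532 and 0.366 without 60M libraries 1 and 2 (2535 against 4763 and 2159 against 5893). The other library of that age then decided alone. With 54.8% of regions in a single library, this raises the count of that age most by construction. These ratios therefore do not show whether the direction rested on 1 library.

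The strongest H3K27me3 regions of one age included several that overlapped H3K4me3 peaks. At 5M, chromosome 17 (39984000 to 39985999) ranked highest, with signal maxima of 482.8 and 259, and lay next to the tallest H3K27me3 peak of both 5M libraries (39978000 to 39982999, 634.3 and 604.5). A 7 kb region on chromosome 1 (90179000 to 90185999) reached 134.1 and 162.1 at 5M. The 5M list also named chromosome 18 (37913000 to 37917999), chromosome 7 (28150000 to 28152999) and chromosome 2 (38208000 to 38210999), each with H3K4me3 in all 4 libraries. The regions on chromosome 11 (3001000 to 3002999) and chromosome 18 (3008000 to 3010999) were the first listed on their chromosomes. At 60M, chromosome 15 (102887000 to 102887999) led with 124.5 and 92.5. Chromosome 1 (90145000 to 90147999), chromosome 7 (12595000 to 12601999), chromosome 8 (123493000 to 123493999) and chromosome 2 (165038000 to 165039999) followed. Of the 12 named regions per direction, 5 of the 5M-only and 1 of the 60M-only regions carried H3K4me3 in all 4 libraries, and 6 and 9 carried it in none. When peaks within 1 kb were merged, 9 of the 12 5M-only and 7 of the 12 60M-only regions still met the rule, because the others bordered a peak of the other age. Both top-ranked regions, on chromosome 17 at 5M and chromosome 15 at 60M, were among the others. So were chromosome 7 (28150000 to 28152999), chromosome 1 (90145000 to 90147999) and chromosome 8 (123493000 to 123493999).

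Broad H3K27me3 domains were fewer at 60M. Peaks of at least 10 kb numbered 222.5 ± 79.9 at 5M and 108 ± 29.7 at 60M (SD, n = 2). In 54 regions both 5M libraries and neither 60M library had such a domain, and in 7 the reverse. One mixed split gave 16 against 2, as lopsided towards the pair with 5M library 2, and the other gave 2 against 2. On chromosome 10 (49497000 to 49510999) a domain of 11 and 14 kb at 5M had no peak at 60M. On chromosome 2 (56952000 to 56966999) the widest peak measured 14 and 15 kb at 5M and 3 and 4 kb at 60M. A gap in the calls divides a domain into shorter peaks, so a narrower widest peak need not mean a shorter domain. The widest domain of both 5M libraries was a 25 kb stretch of chromosome 1 (78187000 to 78211999). Among the 7 domains broad at 60M only, the widest peak on chromosome 5 (144120000 to 144136999) had 17 kb in both 60M libraries against 5 and 8 kb at 5M. That on chromosome 6 (119271000 to 119286999) had 16 and 15 kb against 8 kb in both. Among the 4962 shared regions, 828 (16.7%) were narrower in both 60M libraries and 411 (8.28%) wider. Mixed splits were more lopsided, with 503 against 76 and 344 against 140, the larger numbers for regions wider in the pair with 5M library 2. The direction for age was thus no stronger than that between mixed pairs. The mean covered length per shared region, 3.75 ± 0.411 kb at 5M and 3.42 ± 0.182 kb at 60M, overlapped between the ages.

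Regions with both marks were fewer at 60M, by a difference that also appeared between the 5M replicates. Both marks were present in both libraries of their age at 3201 regions at 5M (7.28% of 43985 H3K4me3 regions) and at 2149 regions at 60M (5.53% of 38836), and 1709 regions had both marks at both ages. Of the 3201 regions, 454 kept H3K4me3 and had no H3K27me3 peak at 60M, 150 had neither mark, 44 had H3K27me3 alone, and at 844 the 60M replicates differed. The opposite step, from H3K4me3 alone to both marks, was made by fewer regions, and 1 region went from neither mark to both. Within the 35229 regions with H3K4me3 in all 4 libraries, H3K27me3 was listed at 8.57% and 11.3% in the 5M libraries and at 8.19% and 7.97% in the 60M libraries. The means were 9.92 ± 1.91% and 8.08 ± 0.157% (SD, n = 2), and the difference was smaller than the spread at 5M. Of these 35229 regions, 578 had H3K27me3 at 1 age only, 454 of them (78.5%) at 5M. As shares of all shared regions, 1.29% were 5M-only and 0.352% were 60M-only. The ratio of 5M-only to 60M-only was 3.66. Mixed splits held fewer regions and were as lopsided towards the pair with 5M library 2, with 146 against 36 (ratio 4.06) and 157 against 41 (ratio 3.83). With single libraries set against each other, 5M library 2 exceeded the 60M libraries with ratios of 3.33 and 3.42, and 5M library 1 with ratios of 1.18 and 1.28. The ratio of 5M library 2 to 5M library 1 was 4.95, higher than in any pair across ages. At equal H3K27me3 list lengths it was 3.34. Across ages, 5M library 1 then gave 1.48 and 1.40, and 5M library 2 gave 3.51 and 3.02. Leaving out 1 library gave ratios of 7.11 and 1.76 without 5M libraries 1 and 2 (1138 against 160 and 582 against 330) and of 1.99 and 1.83 without 60M libraries 1 and 2 (802 against 403 and 721 against 394). The other library of that age then decided alone, so both counts rose by construction.

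In the calls from all 4 libraries, H3K27me3 regions of one age were divided differently on and off H3K4me3 peaks. H3K27me3 regions that overlapped an H3K4me3 peak of any library and were listed at 1 age only numbered 767, of which 589 (76.8%) were 5M-only. Of 2006 such regions that overlapped no H3K4me3 peak, 1014 (50.5%) were 5M-only. The odds ratio between these groups was 3.24 (two-sided Fisher's exact test, p = 1.49e-37, regions as units). Neighbouring regions are not independent, so this p describes these 4 libraries. The contrast changed with the libraries used. Without 5M library 2 the ratios of 5M-only to 60M-only were 1.92 on and 1.87 off the peaks, an odds ratio of 1.03. Without 5M library 1 the odds ratio was 1.77, and without 60M libraries 1 and 2 it was 6.28 and 6.66. Over these 4 settings the ratio ran from 1.65 to 6.22 on the peaks and from 0.248 to 3.52 off them. In each, the remaining library of 1 age decided alone, which moves both ratios by construction. For single libraries set against each other the odds ratio was 2.24 to 3.48 in the 4 pairs across ages, 2.07 between the 5M libraries and 1.01 between the 60M libraries.

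**Figure D3:**
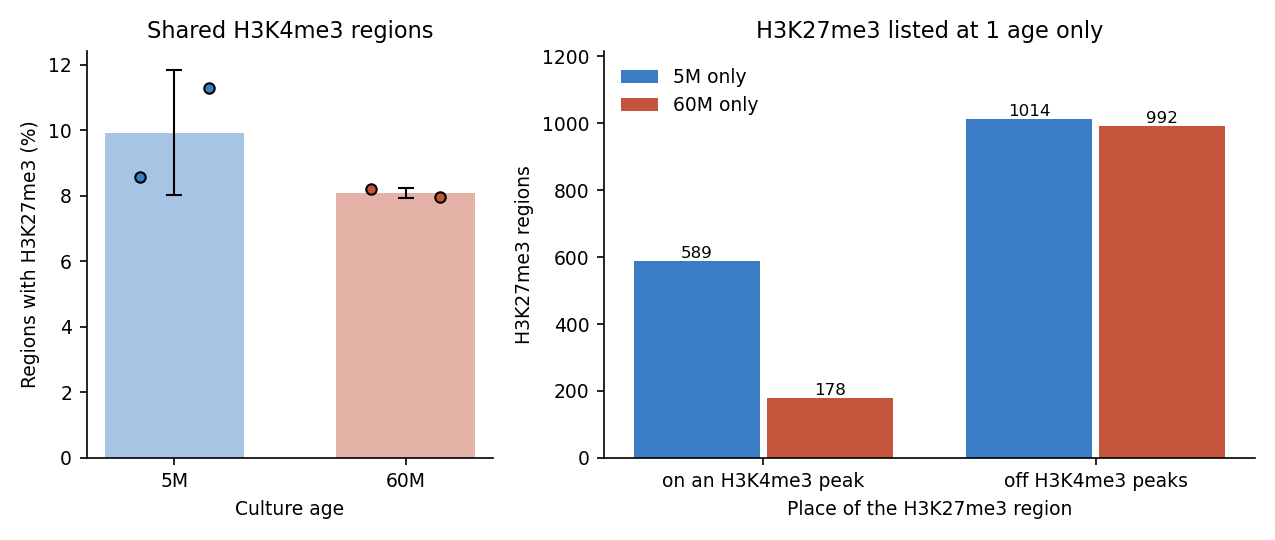
Left, share (%) of the 35229 H3K4me3 regions listed in all 4 libraries that had an H3K27me3 peak, as means of 2 libraries with SD and single libraries as points; right, number of H3K27me3 regions listed at 1 age only, on and off H3K4me3 peaks. On H3K4me3 peaks 589 of 767 regions were 5M-only, and off them 1014 of 2006.

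Regions that changed in H3K4me3 leaned further towards H3K27me3 at 5M than unchanged regions. Of the 5M-only H3K4me3 regions whose H3K27me3 also changed, 150 had H3K27me3 at 5M only and 15 at 60M only, a share of 90.9% (exact 95% interval 85.4 to 94.8%). Of the 60M-only H3K4me3 regions, 27 had H3K27me3 at 5M only and 1 at 60M only, or 96.4% (81.7 to 99.9%). In regions with unchanged H3K4me3 the share was 78.5% (75.0 to 81.8%). Both differed from the unchanged regions by two-sided Fisher's exact tests with Benjamini-Hochberg adjustment over 6 tests, with odds ratios of 2.73 (adjusted p = 0.000354) and 7.37 (adjusted p = 0.0201). They were not shown to differ from each other (Fisher's exact test, adjusted p = 0.476). With 1 H3K27me3 library left out, the other library of its age decided alone, so both counts rose by construction. At 5M-only H3K4me3 regions they were 344 and 19 without 5M library 1, 195 and 27 without 5M library 2, 169 and 50 without 60M library 1, and 175 and 58 without 60M library 2. At 60M-only H3K4me3 regions, in the same order, they were 54 and 1, 29 and 4, 38 and 7, and 36 and 10. At equal list lengths they were 97 and 11 at 5M-only and 47 and 3 at 60M-only H3K4me3 regions, with odds ratios of 2.42 and 4.30 (Fisher's exact test, adjusted p = 0.00568 for both). With each H3K27me3 library left out in turn, the odds ratio ran from 1.65 to 4.10 for the former and from 1.97 to 7.59 for the latter. The lowest value for the 60M-only regions, without 60M library 2, did not pass the exact test (adjusted p = 0.0595). H3K27me3 in all 4 libraries was rarer at changed than at unchanged H3K4me3 regions: 0.799% of the 5M-only, 1.48% of the 60M-only and 4.85% of the unchanged regions had it. By the same exact test, the odds ratios against unchanged regions were 0.158 (adjusted p = 2.27e-59) and 0.294 (adjusted p = 7.53e-18), and 1.86 for 60M-only against 5M-only regions (adjusted p = 0.0106). The intervals and tests cover counting error among regions only. The groups were not matched on strength or length, and a longer region has more room to overlap an H3K27me3 peak.

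A cluster of H3K4me3 regions appeared at 60M on chromosome 18 between 37 and 38 Mb. Of 49 H3K4me3 regions in this window, 13 (26.5%) were listed at 60M only, against 4.46% in the genome, 0 at 5M only and 19 in all 4 libraries. Another 11 were listed in a single 60M library and 0 in a single 5M library. The 13 regions spanned 37098000 to 37995999 and were weak, with a median strength percentile of 15.9 and signal maxima of 40.9 to 200.8 in the 60M libraries. The strongest lay at 37907000 to 37909999, with maxima of 90.3 and 200.8. The window carried 57 H3K27me3 regions, 27 of them in all 4 libraries, and 8 of the 13 gained H3K4me3 regions had H3K27me3 in all 4 libraries, against 36 of all 2437 60M-only regions. It was the only window of 1 Mb to pass in either mark, direction or split (one-sided Fisher's exact test, Benjamini-Hochberg adjusted p = 0.00157 over the 9996 tests of a split). The call was lost when regions were matched on strength, and no window of 1 Mb passed in that version. The window was then expected to hold 3.76 60M-only regions, and the 13 found did not pass (exact Poisson-binomial test, p = 3.71e-05, adjusted p = 0.124 over 9996 tests). With borders shifted by 0.5 Mb, the 2 windows that share the stretch held 6 of 45 and 11 of 55 regions. They did not pass the exact test (p = 0.0144 and 2.67e-05, adjusted p = 1 and 0.068). These were adjusted over fewer tests than the 9996, which makes passing easier.

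**Figure D4:**
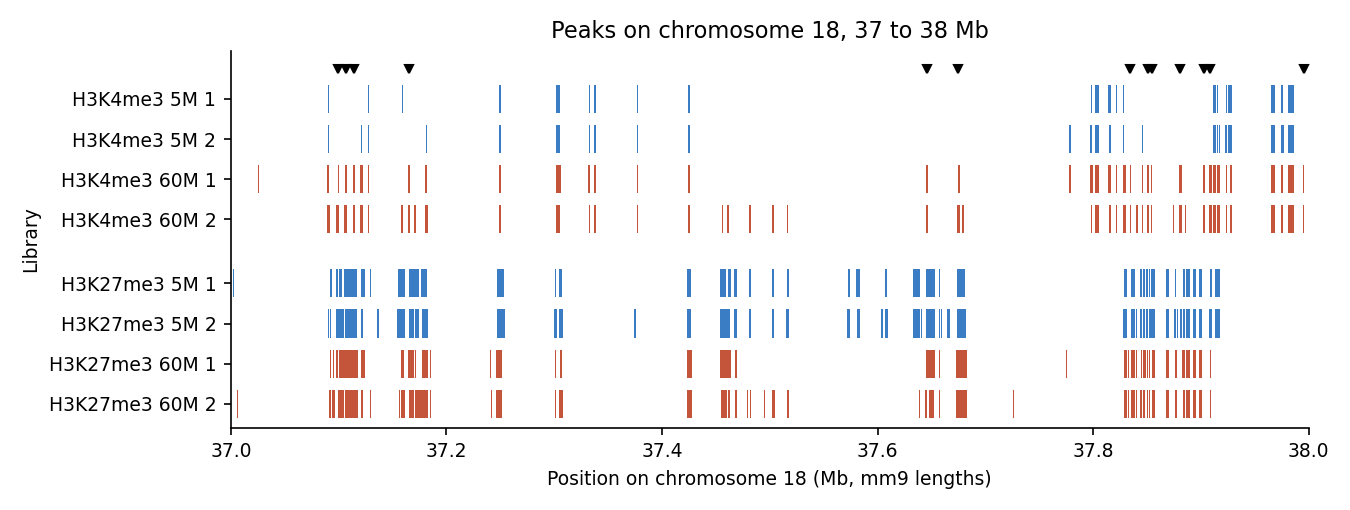
Positions of peaks in the 8 libraries on chromosome 18 from 37 to 38 Mb, one row per library, with triangles at the 13 H3K4me3 regions listed in both 60M libraries and neither 5M library. At 8 of the 13 triangles H3K27me3 peaks are present in all 4 libraries of that mark.

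The ages differed in the share of single chromosomes by small amounts for H3K4me3 and by larger amounts for H3K27me3, whose replicates also differed more. Each chromosome's share of the covered length separated the ages at 13 of 20 chromosomes for either mark, 7 higher and 6 lower at 60M, where chance gives 33.3% or 6.67 chromosomes. For H3K4me3 the ratios of 60M to 5M ran from 0.972 on chromosome 10 to 1.03 on the X chromosome. For H3K27me3 they ran from 0.718 on the X chromosome to 1.12 on chromosomes 4 and 19. Between replicates of one age the ratios ran from 0.982 to 1.04 for H3K4me3, the highest on chromosome 10 at 60M. Those of H3K27me3 ran from 0.883 to 1.15, the highest on the X chromosome at 5M. The X chromosome held 1.29 ± 0.130% of the H3K27me3 length at 5M and 0.927 ± 0.0268% at 60M, and chromosome 4 held 5.60 ± 0.0440% and 6.25 ± 0.122% (SD, n = 2). Shares sum to a whole within a library, so chromosomes are not independent of one another.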

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

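The width difference was chosen for a closer look after the data were examined. The mean H3K4me3 peak width was 0.154 kb higher at 60M than at 5M, and both 60M libraries lay above both 5M libraries. For mean H3K27me3 peak width both 60M libraries lay below both 5M libraries, with a difference of -0.305 kb. At equal list lengths the differences were 0.0628 kb for H3K4me3 and -0.295 kb for H3K27me3. In regions listed in all 4 libraries, the mean H3K27me3 covered length overlapped between the ages. The difference between the marks was not tested for a call, since the 36 arrangements of the libraries within the marks allow no two-sided p below 0.0556.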

How the results depend on the processing

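The minimum strengths, the equal list lengths for widths, H3K27me3 changes and windows, the shifted and 2 Mb windows, the matching on strength, the comparisons of single libraries, the replicate block for values per library, and the leave-one-out values for peak number, width and both marks were chosen after seeing the data. A value counted as moved when it shifted by more than 1 SD between replicates, and a count or ratio when it shifted by more than 1.5 times. Of the alternatives to the main values, 106 stayed within these limits, 37 moved beyond them, 3 lost the call and 4 moved beyond them with a change of direction. Another 5 changed direction within the spread: the H3K27me3 peak number (-42, -643.5 and -280), the H3K27me3 covered length (1.62 Mb) and the H3K4me3 covered length (0.335 Mb). Of those for named regions and smaller classes, 191 stayed, 11 moved and 10 no longer met the rule. Named regions were picked for strength, so equal list lengths and a cut at the median strength of each list could not change them. For region calls, no paired analysis was possible because presence in both 60M libraries and absence from both 5M libraries is the same condition however the libraries are paired. For values per library, a replicate block leaves the mean difference as it is, and 2 pairs allow no two-sided p below 0.5. Differences within the numbers were -2234 and -5778 H3K4me3 peaks (mean -4006) and 0.147 and 0.161 kb of H3K4me3 width, and 2938 and -1595 H3K27me3 peaks and -0.179 and -0.431 kb of H3K27me3 width. The labels give the numbers no shared culture or day. Promoter windows, gene lists and promoters with both marks were not run, for want of an annotation of the build. Depth is unknown, so it cannot be said which missing peaks lie below the detection limit.

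With only the peaks above the median strength of each list, 409 H3K4me3 regions were 60M-only and 1719 5M-only (ratio 4.20), and 674 and 875 H3K27me3 regions. Above percentile 50 the numbers were 24 and 514 (ratio 21.4), and 397 and 665. With signal maxima above the pooled median in both libraries they were 27 and 277 (ratio 10.3), and 268 and 511. These filters leave fewer regions by construction, and the cuts within each list keep more peaks of the longer lists. Equal list lengths brought the H3K4me3 ratio to 1.12, a fall that cutting the longer 5M lists gives by construction, and the width difference to 0.0628 kb. Among peaks above the median of the pooled H3K4me3 list the difference in peak number reversed to 1552.5 more at 60M, that in covered length reversed to 5.31 Mb more, and that in width fell to 0.0396 kb. This cut compares signals of unknown scale, and the median signal was higher at 60M (215.4 and 238.4) than at 5M (183 and 179.4), so a difference in scale could produce the reversals. The cause was not tested. The within minus between age overlap for H3K4me3 was 0.0667 as a share of the shorter list, which is another scale. Counting a mark when either library of an age had it gave 5444 regions with both marks at 5M and 4173 at 60M, a looser condition. The shifted chromosome 18 window held 6 regions, fewer because the stretch was divided. The exact adjusted p of 0.00157 became 2.56e-05 at equal list lengths and 0.000653 in windows of 2 Mb, which passed. It became 1 and 0.068 in the shifted windows and 0.124 with matched strength, which did not pass the exact tests.

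Leaving out 1 library in turn gave 2818 to 4800 H3K4me3 regions at 60M only, with a ratio of 1.42 to 2.46. For H3K27me3 it gave 1489 to 5893 at 60M only and 2159 to 5871 at 5M only, with a ratio of 0.366 to 3.94. Without 60M library 1 (0.532) or 60M library 2 (0.366) the ratio reversed, because the lone library then decides presence at 60M. At unchanged H3K4me3 regions, 582 to 1138 had H3K27me3 at 5M only and 160 to 403 at 60M only.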

Other observations

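Except for the tests of list length and of a copy gain, the tests below were chosen after the results were seen.

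Few regions exchanged one mark for the other. At 27 regions H3K4me3 was 60M-only and H3K27me3 5M-only. The strongest by H3K4me3 lay on chromosome 2 (38192000 to 38192999, mean strength percentile 42.4). Next came 2 regions of chromosome 6 (52113000 to 52115999 and 52120000 to 52120999, percentiles 41.6 and 37.6) and 1 of chromosome 7 (28107000 to 28107999, 38.2). At 15 regions the exchange ran the other way, led by chromosome 9 (91272000 to 91273999, 67.5) and chromosome 1 (36330000 to 36330999, 54.6). Of the 150 regions that lost both marks, the strongest lay on chromosome 8 (3495000 to 3496999), chromosome 6 (48569000 to 48570999) and chromosome 17 (23746000 to 23747999), with percentiles of 58.4, 57.8 and 55.5.

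More H3K4me3 regions were listed at 5M only than at 60M only. Lower sensitivity of both 60M libraries would make shared regions narrower at 60M, and stays open: more were wider in every pair of 1 library per age, but the lowest ratio, 1.67, lay below the 2.25 between the 5M replicates. An origin in weak peaks alone would leave no imbalance among strong ones, but the ratio above percentile 50 was 21.4. That cut keeps more peaks of the longer 5M lists. A common cut at the pooled median signal, whose scale is unknown, kept on average 1552.5 more peaks at 60M. It still gave 277 regions at 5M only and 27 at 60M only, a ratio of 10.3. These counts argue against an origin in weak peaks alone. The longer 5M lists stay open: at equal lengths the ratio was 1.12, and 0.932 to 1.17 with 1 library left out. Cutting the longer 5M lists lowers this ratio by construction, whatever made them longer. The setting therefore cannot decide whether list length caused the excess in number. A hypothesis that may still hold is that strong H3K4me3 sites are lost in long culture more often than gained, which more libraries with known depth could test.

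H3K27me3 at 5M only outnumbered 60M only at unchanged H3K4me3 regions. The excess in 5M library 2 alone stays open as an explanation: 5M library 1 set against each 60M library gave ratios of 1.18 and 1.28, against 4.95 between the 5M replicates. 5M library 1 has the shortest H3K27me3 list, with 12002 peaks. At equal H3K27me3 list lengths its ratios were 1.48 and 1.40, against 3.34 between the 5M replicates. Over all H3K27me3 regions it then gave 1.85 and 1.81 on and 0.848 and 0.845 off H3K4me3 peaks. Lower H3K27me3 enrichment in both 60M libraries would lower strong regions elsewhere too. Away from H3K4me3 peaks the ratio above percentile 50 was 1.12. With 1 library left out it ran from 0.449 to 2.02, which moves by construction. Single libraries across ages, at all strengths, gave 0.516 to 1.15 off the peaks. At equal H3K27me3 list lengths they gave 0.845 to 0.883 off and 1.81 to 3.09 on the peaks. The 5M replicates then gave 1.06 off and 2.12 on them. Equal lengths balance the lists, and these pairs were not limited to strong regions. Enrichment and a single library therefore cannot be told apart from a change tied to H3K4me3. Culture age remains open as a biological explanation, untested, as does the way of fragmentation, which the labels do not tie to libraries.

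On chromosome 18 between 37 and 38 Mb, 13 regions were 60M-only. Weak peaks near the calling limit stay open as an explanation: regions matched on strength gave an expected 3.76, and the excess of 3.45 times did not pass (exact Poisson-binomial test, adjusted p = 0.124). A copy gain of the stretch could also raise weak peaks. Shared H3K4me3 regions there were wider at 60M in 3 of 19 cases (15.8%, exact 95% interval 3.38 to 39.6%), 2.12 times the share in the genome, while H3K27me3 was 60M-only at 3 regions and 5M-only at 4. These are too few to decide, so neither can be told apart from a local gain of H3K4me3 with age.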
